A study of Homo sapiens with 21 samples.

How the data were processed

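Paraspinal muscle, the deep muscle that runs along the spine, was taken from 10 patients with adolescent idiopathic scoliosis (AIS), a sideways and rotational curve of the spine with no known cause, and from 5 adult control patients. In 6 AIS patients the labels name a piece from the concave (inner) and a piece from the convex (outer) side of the curve, in 2 a concave piece only, and in 2 a convex piece only. That gave 8 AIS concave, 8 AIS convex and 5 control libraries. Per the labels, RNA was extracted with TRIzol from frozen tissue, poly-A RNA was selected, cDNA was primed with random hexamers, and libraries were sequenced as read pairs on an Illumina NovaSeq. The submitters' processing notes name Trim Galore, DESeq2 and the genome build hg19, without versions. The aligner, the counting tool and the annotation are not given in the sources used here.

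The authors deposited one table of TPM values, with 1 column per library and 26259 named genes. TPM is the share of a library's transcripts that a gene holds, corrected for transcript length and scaled to a fixed sum, so it keeps no read totals. The depth of each library is therefore unknown, and no counting interval or detection floor could be given. A TPM is a share of the library, so a large rise of abundant genes lowers all others. The reference annotation at hand is for a later build than hg19, so no coordinates are given. Of 26124 gene symbols left after the removal described next, 25075 were found in the reference tables.

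The 8 AIS convex columns stood 1 line below their gene names in the deposited table. Their last values lay in 1 line without a gene name, where all other columns were empty, and each of these columns summed to 1000000.00 without its first value, as the other columns did with all their values, except 1 concave library that summed to 1000005.44 for an unknown reason. Across genes, the mean log2 value of the convex columns correlated with the mean of the other columns at r = 0.390 as deposited and at r = 0.997 after a move by 1 line. In each of 27 blocks of 1000 lines the correlation was at least 0.989 after the move and at most 0.547 before it. The convex values were therefore moved by 1 line, and the names as deposited were run as an alternative. The name of 1 control column has its letters in another order than the label and was mapped to that label. 3 columns match no label and were not used.

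XIST, Y-linked genes and other sex-informative genes, 135 in all, were removed before any test. Genes with at least 1 TPM in at least 5 of the 21 libraries were kept, which left 13802. Values were log2(TPM + 1). Differences were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided, statmod 1.5.0 for the patient correlation), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale. AIS was compared with control by patient: both sides of a patient were averaged, which gave 10 values against 5. Concave and convex libraries were compared 8 against 8 without the patient as a term, and each side was compared with the 5 controls. Fits with the patient as a fixed block in the 6 pairs and as a random effect (correlation of the sides of a patient 0.250) were run beside the comparison of sides. Numbers of AIS and control patients name different people and were not paired.

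Before the data were examined, 46 gene lists for muscle, its other cell types and handling of tissue were fixed, together with the comparisons, most alternatives and the rule for naming genes. 45 lists had at least 5 tested members. The list of mitochondrially encoded genes had none, because the table holds none of them. Lists were tested with camera from limma, two-sided, at a preset correlation of 0.01 between genes, and again with an estimated correlation. A rotation test of direction (fry) was run beside them. Named genes were the 10 with the largest rise and the 10 with the largest fall among genes past the threshold whose higher group had a mean of at least 5 TPM, and up to 4 members with the smallest p of each list described. HLA, immunoglobulin and T cell receptor genes, genes with common deletions in people and clone-named transcripts were not named. Library measures were compared by exact permutation, with patients as units.

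The fits were tested on simulated data of the same size, in 5 simulations with 200 changed genes each. Each simulated gene had normal noise with its spread pooled over both groups. For AIS against control, 53.7% of genes changed by 1 on the log2 scale were called, 96.7% of those changed by 2, and 4.1% of calls were wrong. For concave against convex the values were 64.5%, 96.1% and 5.1%. A list moved by 1 was called in 5 of 5 simulations in each comparison. Unmoved lists were called 1 time in 220 for AIS against control and 0 times in 220 for concave against convex. The simulated genes varied independently of each other, so these last counts do not show how often camera calls an unmoved list among correlated genes. Both simulated groups had the same spread, so the shares of wrong calls do not cover genes whose spread differs between the groups.

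Alternatives covered the pseudocount, the filter on low values, the scaling (median-of-ratios and quantile), the settings of the empirical Bayes step, library weights, a fold change minimum, the mean of the adipocyte or immediate early genes as a covariate, all libraries with the patient as a random effect, and each patient left out in turn. For the named genes of AIS against control an exact permutation of patients was also run, with p adjusted over these genes only. The fit without 3 libraries and the names as deposited were added after seeing the data. A rescaling without mitochondrially encoded genes and the share of these genes per library could not be run. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.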

Results

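The data comprised 21 poly-A RNA-seq libraries of paraspinal muscle: 8 from the concave and 8 from the convex side of the curve of 10 patients with adolescent idiopathic scoliosis (AIS), and 5 from adult controls. Values were TPM as the authors deposited them, with the convex columns moved by 1 line to meet their gene names. Read depth was unknown. Each library held between 10624 and 13466 genes at 1 TPM or more. AIS and control patients also differed in age group, and the labels do not give the level of the spine or the time to freezing.

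AIS muscle held far more mRNA of immediate early genes, which cells transcribe within minutes of a stimulus, than control muscle. Of the immediate early genes tested, 17 of 23 rose past the threshold, as did 11 of 15 fast-twitch fibre genes and 9 of 20 genes of glycolysis and glycogen, while 5 of 11 genes of developing or regenerating fibres fell past it. These lists passed at a preset correlation between genes but not with an estimated one (adjusted p = 0.0544 for each of the first 3 and 0.206 for the last with an estimated correlation). FOS was 53.1-fold and MYH1, the myosin heavy chain of fast 2X fibres, 25.7-fold higher in AIS, while ACTC1, the cardiac actin that developing skeletal muscle also expresses, was 21.1-fold lower. Fold values here and below come from the difference of mean log2(TPM + 1) values and are not ratios of the mean TPM values. The comparison addressed how the muscle beside the curve differs from muscle of people without AIS. Of 13802 genes, 345 passed the limma test, 187 higher and 158 lower in the 10 AIS patients than in the 5 controls. 257 of them differed by at least 1 on the log2 scale. Without adjustment 2003 genes had p under 0.05, where chance gives 690. In 124 of the 345 genes the groups did not overlap, as 0.993% of all genes did and 0.067% would by chance. The median of all genes was −0.11 on the log2 scale, and scaling moved it to about −0.01.

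The count depended on the setting: it was 731 (438 higher, 293 lower) with median-of-ratios scaling, 957 (550 higher, 407 lower) with quantile scaling, 740 (175 higher, 565 lower) without control replicate 2, and 1012 (281 higher, 731 lower) without the 3 libraries with the fewest genes, a fit chosen after seeing the data. It was 1156 (188 higher, 968 lower) with the adipocyte mean as a covariate and 29 (6 higher, 23 lower) with the immediate early mean as a covariate, where 46 of the 50 named genes called for AIS against control lost the call and the median standard error of the named genes was 0.51 in place of 0.38. The 3 libraries with the fewest genes were AIS concave replicate 1, AIS convex replicate 5 and control replicate 2. The fit without them thus also left out control replicate 2.

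All 23 members of the immediate early list had a positive log2 fold change (median 2.20), and 17 of them rose (18 adjusted over the list alone). FOS, a subunit of the transcription factor AP-1, was at 1369.7 ± 800.1 TPM (SD, n = 10 patients) in AIS and 47.4 ± 58.8 TPM (n = 5) in controls, a log2 fold change of 5.73 ± 0.64 (SE, limma adjusted p = 2.44e-05). EGR1, a zinc finger transcription factor of the same early response, was at 762 ± 538 against 29.1 ± 29.4 TPM (5.06 ± 0.56, adjusted p = 2.33e-05). FOSB rose by 5.17 (adjusted p = 9.32e-05), NR4A1 by 3.80 (8.98e-05), ZFP36, whose protein promotes decay of cytokine mRNAs, by 3.15 (0.00200) and IER2 by 2.83 (5.16e-05). All 10 patients were above the control mean for each of these 6 genes. The list passed against the other genes (camera adjusted p = 7.88e-40) but not when the correlation between genes was estimated (adjusted p = 0.0544 with an estimated correlation). By side, 17 of 23 members rose on the concave side against control (camera adjusted p = 5.72e-37, adjusted p = 0.0573 with an estimated correlation) and 15 of 23 on the convex side, where the list also passed with the estimated correlation (camera adjusted p = 2.18e-50, adjusted p = 0.0357 with an estimated correlation). It was the 1 list of 45 to do so there. List tests of each side against control were not among the list tests fixed beforehand. Between the sides this list did not pass (camera adjusted p = 0.475), so these values do not show that the sides differ. With the immediate early mean itself as a covariate FOS was at 2.47 ± 0.66 and no longer passed (adjusted p = 0.0807, the highest of its alternatives, the lowest being 9.36e-07).

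The NF-kappaB and inflammatory cytokine list had a median of 0.95, and 4 of 18 members rose (9 adjusted over the list alone). CXCL2, a neutrophil attractant, rose by 3.27 (adjusted p = 0.00316), SOCS3, an inhibitor of cytokine signalling, by 3.18 (0.0111), and CXCL8 by 1.74 (0.0106), each in 10 of 10 patients. SELE, an adhesion molecule of activated endothelium, rose by 1.98 in 9 of 10 patients (0.0274), a call lost without control replicate 1, 3 or 5 (adjusted p up to 0.0712). The list had a camera adjusted p of 1.03e-08 (adjusted p = 0.388 with an estimated correlation). In the heat shock and chaperone list 4 of 21 members rose, and adjusted over the list alone 4 rose and 2 fell. The risers were the inducible chaperones HSPA1B (1646 ± 772 against 207 ± 239 TPM, log2 fold change 3.30, adjusted p = 3.09e-04), HSPA1A (2.76, 0.00106), HSPA6 (2.87, 0.00361) and DNAJB1 (2.65, 0.00102). HSPA1A and HSPA1B are near-identical copies, so the division of reads between them is uncertain. The list median was 0.21 (camera adjusted p = 8.11e-05, adjusted p = 0.638 with an estimated correlation).

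Of 15 fast fibre genes 11 rose (12 adjusted over the list alone), and all 15 had a positive log2 fold change, with a median of 2.02. MYH1 was at 1191 ± 499 TPM in AIS and 62.9 ± 56.4 TPM in controls (4.68 ± 0.61, adjusted p = 1.50e-04). ATP2A1, the calcium pump of the fast fibre reticulum, was at 2349 ± 536 against 366 ± 430 TPM (3.52 ± 0.54, adjusted p = 8.65e-04). MYBPC2 rose by 2.99 (0.00123) and the fast troponin TNNI2 by 2.39 (0.00206), and the 10 patients lay above the control mean in all 4 genes. With the immediate early mean as a covariate MYH1 was at 4.19 ± 1.06 and did not pass (adjusted p = 0.0655, the highest of its alternatives, the lowest being 1.38e-04). The list had a camera adjusted p of 6.87e-24 (adjusted p = 0.0544 with an estimated correlation). The slow fibre list did not pass (median −0.15, camera adjusted p = 0.648). 1 of its 14 members fell and adjusted over the list alone 1 rose and 3 fell. MYL6B fell by 0.98 (0.00693), while MYOZ2 (−0.94, 0.0875), CASQ2 (−0.87, 0.175) and ATP2A2 (0.79, 0.101) did not pass.

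Glycolysis and glycogen genes had a median of 0.94, and 9 of 20 rose (15 adjusted over the list alone). ALDOA rose by 1.43 (adjusted p = 5.25e-05), PYGM, the muscle glycogen phosphorylase, by 1.47 (5.71e-05), ENO3 by 1.74 (1.71e-04) and GAPDH by 1.14 (4.76e-04), in 10 of 10 patients each. The list had a camera adjusted p of 1.04e-23 (adjusted p = 0.0544 with an estimated correlation). In the excitation-contraction coupling list 2 of 17 members rose (7 adjusted over the list alone; median 0.45, camera adjusted p = 5.06e-08, adjusted p = 0.388 with an estimated correlation). They were the potassium channel KCNA7 (1.37, 8.98e-04) and the chloride channel CLCN1 (1.19, 0.0333), which passed in 6 of 15 fits that left out 1 patient. JSRP1 (0.66, 0.0608) did not pass. Nuclear genes of oxidative phosphorylation had a median of 0.06, and 1 of 40 rose (2 adjusted over the list alone; camera adjusted p = 0.0023, adjusted p = 0.797 with an estimated correlation). This was COX6A2, the muscle form of a cytochrome c oxidase subunit (0.74, 0.0340), which passed in 7 of 15 fits that left out 1 patient. The list lost its call without control replicate 3 (median −0.02, camera adjusted p = 0.347), AIS replicate 1 (0.0544) or control replicate 4 (0.0616).

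Genes of developing and regenerating fibres had a median of −1.42, and 5 of 11 fell (8 adjusted over the list alone; camera adjusted p = 7.32e-07, adjusted p = 0.206 with an estimated correlation). ACTC1 was at 76.4 ± 69.0 TPM in AIS and 1378 ± 802 TPM in controls (−4.40 ± 0.47, adjusted p = 2.33e-05). TNNT2, the cardiac troponin T of early muscle, fell by 2.32 (0.00339) and MYH3, embryonic myosin, by 2.23 (0.0111, but 0.0512 without control replicate 5). MYH8, perinatal myosin, fell by 1.67 (0.0344) and passed in 7 of 15 fits that left out 1 patient. MYBPH, a myosin binding protein in no list, had the largest fall of the named genes, from 483 ± 311 TPM in controls to 21.5 ± 35.4 TPM in AIS (−4.80 ± 0.80, adjusted p = 0.00166). The denervation and neuromuscular junction list did not pass (median −0.42, camera adjusted p = 0.260), with 1 of 15 members past the threshold as higher and 2 as lower (1 and 5 adjusted over the list alone). ACHE, acetylcholinesterase, rose by 1.09 (0.0124). RUNX1 fell by 1.65 (0.0190, lost without control replicate 1 or 4, adjusted p up to 0.0736) and DOK7 by 0.84 (0.0386, passed in 4 of 15 such fits), and CHRNA1 did not pass (−1.68, 0.0504). The myokine list did not pass (median −0.45, camera adjusted p = 0.320), with 1 of 17 past the threshold as higher and 3 as lower, also adjusted over the list alone. APLN fell by 1.37 (0.0106), FGF6 by 1.67 (0.0259, lost without control replicate 4 or 5, adjusted p up to 0.106) and MUSTN1 by 1.05 (0.0372, passed in 7 of 15 such fits), and FNDC5 rose by 0.79 (0.0389, passed in 6 of 15).

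Markers of other cells moved in both directions. Of the mast cell genes, TPSAB1 fell by 2.39 (adjusted p = 0.0274, lost without control replicate 1, 3 or 4, adjusted p up to 0.0706), TPSB2 by 2.17 (0.0159, but 0.0520 without control replicate 3) and CPA3 by 1.47 (0.0106). KIT did not pass (−0.46, 0.347). TPSAB1 and TPSB2 are near-identical, so the division of reads between them is uncertain. The neutrophil and mast cell list as a whole did not pass: 3 of 12 members fell, over all genes and adjusted over the list alone, its median was 0.33, its mean −0.24, and its test pointed down (camera adjusted p = 0.886). Of 19 adipocyte genes 2 rose (5 adjusted over the list alone; median 0.72, camera adjusted p = 7.58e-08, adjusted p = 0.388 with an estimated correlation). These were GPD1 (1.51, 9.59e-04) and PLIN4 (1.18, 0.00736), both of which muscle fibres also express, and PCK1 did not pass (1.15, 0.0786). Of 26 collagen and matrix genes 1 fell (4 adjusted over the list alone; median −0.58, camera adjusted p = 7.17e-04, adjusted p = 0.797 with an estimated correlation). It was the proteoglycan BGN (−1.75, 0.0125, but 0.0504 without control replicate 1), and TIMP1 did not pass (−1.09, 0.0577).

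Other genes among the largest falls belonged to no list. PRUNE2 was at 1.79 ± 1.08 TPM in AIS and 34.1 ± 24.2 TPM in controls (−3.45, adjusted p = 2.20e-05). SAA1, an acute phase protein, fell by 3.44 (0.00354), METTL21C, a muscle lysine methyltransferase, by 2.77 (0.00577), BEX2 by 2.54 (0.00197) and SCT, the hormone secretin, by 2.33 (0.0123). BCYRN1 fell by 3.30 (0.00229), but copies of this short RNA lie across the genome and its reads are hard to place. Each of the 6 was below the control mean in 10 of 10 patients. In all, 23 of 45 lists passed, 17 higher and 6 lower, and 0 of them with an estimated correlation between genes, where 5 had an unadjusted p under 0.05 in camera. A rotation test (fry), which asks for a shared direction and does not compare a list with other genes, passed for the immediate early and the glycolysis list (adjusted p = 0.0048 each) and for the fast fibre and the developing fibre list (0.0079 each). It did not pass for excitation-contraction coupling (0.173), NF-kappaB (0.376), adipocyte (0.424), heat shock (0.432), matrix (0.443) or oxidative phosphorylation genes (0.658).

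**Figure D1:**
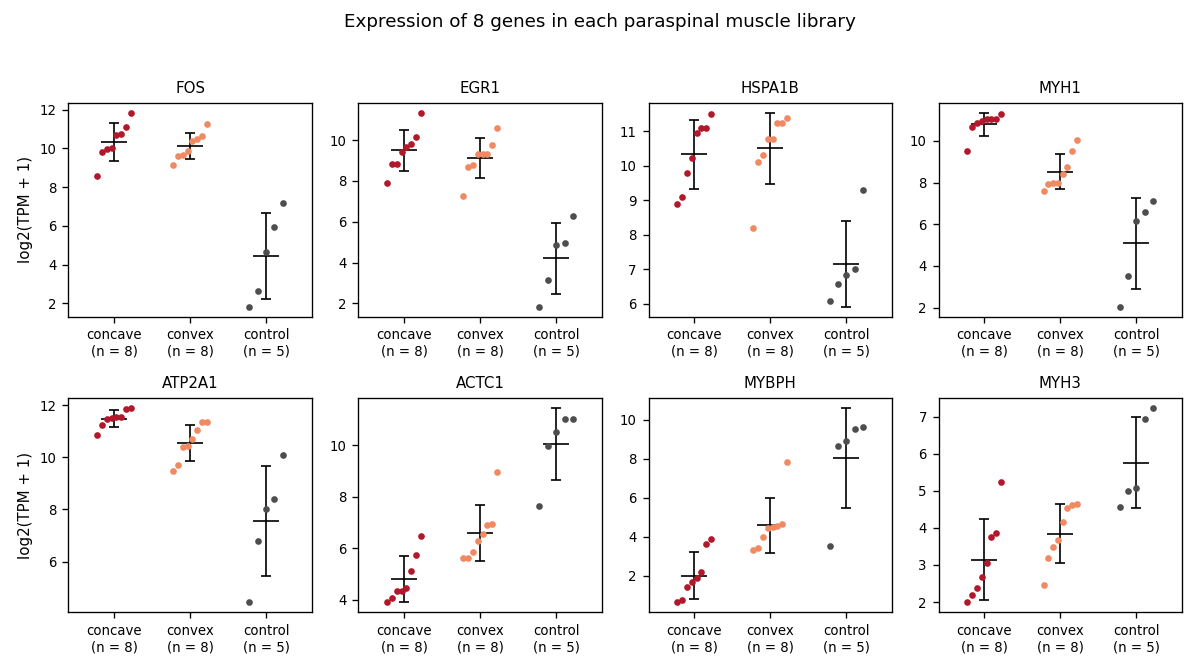
Expression of 8 named genes in each library as log2(TPM + 1), for AIS concave (8 libraries), AIS convex (8) and control (5) muscle; points are libraries, and the line and bar are the mean and SD, on an axis that differs between panels and does not start at 0. FOS, EGR1, HSPA1B, MYH1 and ATP2A1 have higher means and ACTC1, MYBPH and MYH3 lower means in AIS than in control muscle, and MYH1 has a higher mean on the concave (1883 TPM) than on the convex side (433 TPM).

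Between the sides of the curve, MYH1 was the 1 gene past the threshold in the fit without the patient as a term. It was 4.86-fold higher on the concave side, at 1883 ± 537 TPM (SD, n = 8 libraries) against 433 ± 297 TPM (n = 8) on the convex side, and all 8 concave libraries lay above the convex mean (log2 fold change 2.28 ± 0.31, limma adjusted p = 0.00706). The sides overlapped: the highest convex library was at 10.02 and the lowest concave library at 9.50 in log2(TPM + 1). This comparison asked whether muscle on the inner and outer side of the curve differs in the same disease. 1 of 13802 genes passed, and 869 had an unadjusted p under 0.05, where chance gives 690. Of 100 splits that part the 6 pairs, the real one included, 5 gave as many genes past the threshold. MYH1 also passed with the patient as a fixed block in the 6 pairs (2.54, adjusted p = 0.0412). It no longer passed without AIS replicate 4 (adjusted p = 0.0880), 6 (0.0764) or 8 (0.0773), which left 0 genes, while 10 genes passed without AIS replicate 3, 9 without AIS replicate 9 and 2 without AIS replicate 5. With the patient as a random effect 46 genes passed (24 higher and 22 lower on the concave side), and 16 with array weights. Over all its alternatives the adjusted p of MYH1 ran from 0.00142 to 0.0880.

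In the fast fibre list all 15 members were higher on the concave side, with a median of 0.82. 1 passed over all genes and 12 adjusted over the list alone (camera adjusted p = 1.13e-21, adjusted p = 0.0962 with an estimated correlation). MYBPC2 (1.39, adjusted p = 0.0673), TNNC2 (0.98, 0.124) and ATP2A1 (0.94, 0.225) did not pass over all genes. With the patient as a random effect MYBPC2 (1.41, 0.0204, in a range of 0.0204 to 0.260 over its alternatives) and TNNC2 (0.97, 0.0369, in 0.0369 to 0.499) did, but with the patient as a fixed block in the 6 pairs neither did (adjusted p = 0.0744 and 0.121). The slow fibre list was lower (median −0.24, camera adjusted p = 2.04e-08, adjusted p = 0.214 with an estimated correlation). None of its 14 members passed over all genes and 5 did adjusted over the list alone. MYL6B (−1.09, 0.0710), CSRP3 (−1.02, 0.0710), MYOZ2 (−1.21, 0.0871) and CASQ2 (−0.88, 0.280) did not pass, and with the patient as a random effect MYL6B (−1.13, 0.0237, in 0.0237 to 0.342), CSRP3 (−0.99, 0.0318, in 0.0318 to 0.342) and MYOZ2 (−1.20, 0.0236, in 0.0236 to 0.410) did, while with the fixed block they did not (adjusted p = 0.0958, 0.157 and 0.0744). Glycolysis and glycogen genes had a median of 0.47, with 0 of 20 past the threshold over all genes and 12 adjusted over the list alone (camera adjusted p = 1.22e-12, adjusted p = 0.158 with an estimated correlation). Its members with the smallest p were PHKG1 (0.57, 0.185), FBP2 (0.69, 0.188), PGM1 (0.63, 0.257) and PYGM (0.47, 0.292).

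Of the other lists, excitation-contraction coupling (median 0.27, camera adjusted p = 1.94e-07, adjusted p = 0.210 with an estimated correlation) and adipocyte genes (0.45, 1.56e-04, adjusted p = 0.810 with an estimated correlation) were higher on the concave side. Markers of fibro-adipogenic progenitors were lower as a list (−0.61, 2.04e-08, adjusted p = 0.663 with an estimated correlation), as were those of endothelium (−0.41, 2.14e-04, adjusted p = 0.810 with an estimated correlation) and of macrophages (−0.45, 2.14e-04, adjusted p = 0.810 with an estimated correlation). No member of these 5 lists passed over all genes, and adjusted over the list alone 1 did in each of the first 2 lists and 0 of 16, 0 of 18 and 0 of 20 in the last 3. Immediate early genes did not pass between the sides (0.08, camera adjusted p = 0.475). In all, 18 of 45 lists passed, 4 higher and 14 lower, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05 in camera. The rotation test passed for the fast fibre list (adjusted p = 0.0435) and not for the glycolysis (0.0923) or the slow fibre list (0.136). Nor did it pass for excitation-contraction coupling (0.136), fibro-adipogenic progenitor (0.664), adipocyte, endothelium or macrophage genes (0.812 for each of the last 3).

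**Figure D2:**
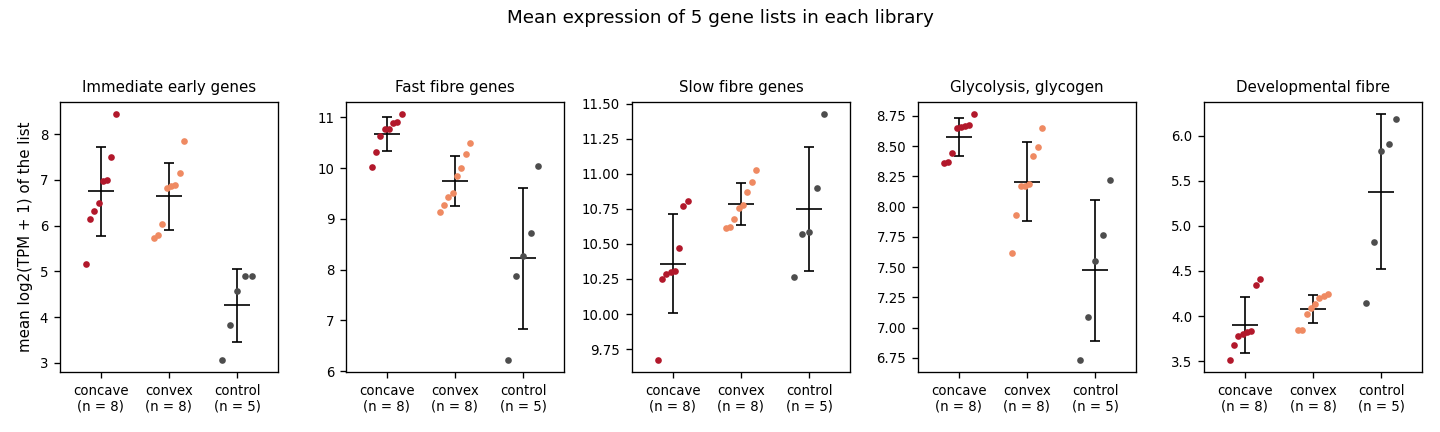
Mean log2(TPM + 1) of 5 gene lists in each library, for AIS concave (8 libraries), AIS convex (8) and control (5) muscle; points are libraries, and the line and bar are the mean and SD, on an axis that differs between panels and does not start at 0. The fast fibre mean was 10.67 ± 0.34 on the concave side, 9.75 ± 0.49 on the convex side and 8.23 ± 1.39 in controls, and the immediate early mean was 6.75 ± 0.98, 6.64 ± 0.74 and 4.25 ± 0.80.

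Both sides of the curve differed from control muscle, and their fold changes correlated, with a lower r once each side had its own, fewer controls. The concave side had 368 genes past the limma threshold (202 higher, 166 lower, 175 without overlap, 1802 at an unadjusted p under 0.05), and the convex side 111 (79 higher, 32 lower, 61 without overlap, 1301 unadjusted). 8 libraries against 5 part without overlap in 0.155% of genes by chance. On both sides 72 genes were higher and 23 lower, where independent lists would share 1.16 and 0.38. In the median of 100 simulations of unchanged groups against the same controls, 0 were shared (at an unadjusted p, 874 observed and 212.5 simulated). These simulations drew genes independently with the same spread in all groups, so they do not bound the overlap that the shared controls give in the data. The concave count was 205 without a filter on low values, 755 and 899 with median-of-ratios and quantile scaling, 567 (227 higher, 340 lower) without the 3 libraries with the fewest genes, 2381 (141 higher, 2240 lower) with the adipocyte mean and 116 (12 higher, 104 lower) with the immediate early mean as a covariate. The convex count was 31 without a filter, 184 and 211 with the scalings, 331 (117 higher, 214 lower) without the 3 libraries, 186 (135 higher, 51 lower) without AIS convex replicate 5, 185 (71 higher, 114 lower) without control replicate 2, and 0 with the immediate early mean as a covariate (2234 at an unadjusted p).

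Across genes, which are not independent replicates, the fold changes of the sides correlated at r = 0.834 (Spearman 0.763). Simulated unchanged groups against the same 5 controls gave 0.686, since both fold changes contain the same control values and 6 patients gave both sides. The simulation drew genes independently, each with 1 spread for all groups. In the data the fast fibre mean had an SD of 1.39 in controls, 0.34 on the concave and 0.49 on the convex side. The immediate early mean had an SD of 0.80 in controls, less than the 0.98 of the concave and more than the 0.74 of the convex side. A wider spread of controls alone would raise r, so 0.834 against 0.686 does not show a shared effect. With separate controls for each side r was 0.426 (0.214 to 0.524 over 20 splits; Spearman 0.281), and 53.9% of genes had the same sign, against 79.6% with shared controls. With different patients on each side r was 0.777, but both sides still shared the 5 controls, and no unchanged groups were simulated for that setting. With both separated r was 0.402 (0.127 to 0.540 over 200 splits, Spearman 0.267, 55.3% with the same sign). Fewer controls for each side make noisier fold changes, which lowers r by itself. The covariance of the fold changes was 0.168 with shared controls, 0.112 with separate controls and 0.112 with both separated. It was 0.066 in the simulated groups, which shared their controls. No unchanged groups were simulated with separate controls, so the values with separate controls were not tested. The test of a difference between these effects is the comparison of the sides given above, where MYH1 passed.

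The libraries of AIS and control patients did not differ detectably in 2 general measures. The 10 highest genes took 25.2 ± 3.03% of TPM in AIS (SD, n = 10 patients) and 27.6 ± 9.64% in controls (n = 5), exact permutation p = 0.496 (adjusted p = 0.908 over 4 tests). The number of genes at 1 TPM or more was 12516 ± 740 in AIS and 12881 ± 799 in controls (exact permutation p = 0.401, adjusted p = 0.908).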

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

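The tests of the cell markers, the 5 heat shock genes, the slow fibre median, the HOX genes outside the list test, MYH1 on the difference between the sides and its sum with its paralogs, the fast minus slow mean and the numbers of genes at an unadjusted p were chosen only after the result was seen. Far values were sought in 258 sets of libraries, each 1 gene or measure in 1 group. 19 held a library far from the rest, where chance gives about 1 in 20, or 12.9.

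On the concave side 17 of 23 immediate early genes passed the threshold as higher than in control muscle (camera adjusted p = 0.0573 for the list with an estimated correlation, not passed), and 15 of 23 on the convex side (camera adjusted p = 0.0357 with an estimated correlation, passed). Between the sides the list did not pass (camera adjusted p = 0.475 at the preset correlation). More vascular, stromal or immune cells in the AIS pieces would raise the markers of such cells, but the median log2 fold change of 69 markers was −0.41 (quartiles −0.67 and −0.14), far below the 2.20 of the immediate early list. Surgical handling and time to freezing that differed between the groups could give the same picture: HSPA1A, HSPA1B, HSPA6, DNAJB1 and HSPH1, of which the first 4 were already known to pass, had a median of 2.76, but the 21 genes of the heat shock list had 0.21, with 7 of them lower. It cannot be told apart from a difference between AIS and control muscle, because the labels give no handling times and no control piece handled like the AIS pieces. Age group and disease differ between the same groups and stay open, untested.

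Of 15 fast fibre genes 11 passed the threshold as higher in AIS than in control muscle, but the list did not pass with an estimated correlation (camera adjusted p = 0.0544 with an estimated correlation). A larger share of muscle fibres would raise slow fibre genes alike, but these had a median of −0.15 (quartiles −0.28 and 0.09), against 2.02 for the fast list (quartiles 0.93 and 2.96). If handling moved both, fast fibre and immediate early means might rise together; over 10 AIS patients r was −0.48 (permutation p = 0.156; Spearman −0.50, p = 0.143; 1 relation tested; r = 0.00 without the 2 patients farthest out), which is too wide a spread to decide. Pieces from another level of the spine remain open, as do age group and disease, untested. Of 26 HOX genes, which mark levels along the body, 0 passed in limma, but 6 had an unadjusted p under 0.05, their median absolute change was 0.35 against 0.23 for all genes, and the cervical and the mid thoracic HOX list passed camera (adjusted p = 0.0075 and 0.0076, but adjusted p = 0.638 and 0.388 with an estimated correlation).

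MYH1 was higher on the concave than on the convex side, so that its difference from control was larger there by 2.28 on the log2 scale. An exact permutation of the libraries without the pairs gave p = 3.11e-04, where the smallest possible is 1.55e-04. By pairs MYH1 was higher in 6 of 6 patients (2.54 ± 1.00 SD, exact sign-flip p = 0.03125, the smallest possible). MYH1 was picked by its call between the sides, so neither p is a new test of it. Reads moved between MYH1 and its paralogs MYH2 and MYH4 would leave their sum alike, but the sum was higher on the concave side. It was at 3617 ± 908 against 1864 ± 957 TPM (SD, n = 8 each, exact permutation p = 0.0031 without the pairs). By pairs it was higher on the concave side in 6 of 6 patients (1.32 ± 0.64 SD, exact sign-flip p = 0.03125, the smallest possible). The fast minus slow mean was higher on the concave side in 6 of 6 patients (1.42 ± 1.00 SD, exact sign-flip p = 0.03125, the smallest possible). This mean holds MYH1 itself, and the direction of both lists was known beforehand, so it cannot decide whether the share of muscle fibres differed. The slow fibre mean, which a larger share would raise, was higher on the concave side in 1 of 6 patients (−0.42 ± 0.38 SD, exact sign-flip p = 0.0625). A processing difference of the convex columns that touches many genes cannot be told apart from a difference between the sides: 869 genes had an unadjusted p under 0.05 (690 by chance), 1491 and 1665 with the 2 scalings, 1298 with the patient as a random effect and 1838 with the patient as a fixed block, and all convex libraries shared the displaced columns. A difference of fibre type between the sides stays open with it; without AIS replicate 4, 6 or 8 the log2 fold change of MYH1 was 2.17, 2.17 and 2.22, near the 2.28 of all patients, but its adjusted p (0.0880, 0.0764 and 0.0773) no longer passed.

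Other splits of the samples were counted for each comparison, 100 splits at a time with the real one among them. For AIS against control the real split gave the most genes (345 genes, highest other 17). That is 1 of 100 splits with as many, the smallest share that 100 splits can give, so chance is unlikely for the genes but not excluded. For the number of lists, 10 of 100 splits gave as many (23 lists, where the others gave 6 to 28), so chance stays open. The same smallest share was found for the concave side against control (1 of 100, 368 genes, highest other 3). It was also found for the convex side against control (1 of 100, 111 genes, highest other 4), so chance is unlikely in both. For concave against convex, among splits that part the 6 pairs as the real one does, chance could not be excluded for the number of genes (5 of 100 splits; 1 gene, highest other 5) or of lists (18 of 100; 18 lists, highest other 24). Among 100 splits that ignored the pairs, 1 gave 30 genes, several times the real count, and every other gave 0 or 1. Why that split gave so many genes was not tested.

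1 library lay far from the rest of its group in each of the following, in log2(TPM + 1) and with the group median beside it. In AIS concave muscle the lowest value was 9.50 for MYH1 (median 10.99), 3.48 for KCNA7 (4.46), 5.02 for TIMP1 (6.38) and 1.19 for POSTN (4.01), and the lowest list mean was 2.86 for myokines (3.87) and 3.04 for collagen and matrix (5.19). In AIS convex muscle the lowest value was 8.20 for HSPA1B (10.78), 8.27 for HSPA1A (11.10), 8.79 for ATP2A2 (10.65) and 2.26 for CLCN1 (4.13), and the highest was 7.83 for MYBPH (4.47), 8.95 for ACTC1 (6.41) and 11.39 for COX7A1 (10.37). In controls the highest value was 9.31 for HSPA1B (6.83) and the lowest 3.55 for MYBPH (8.90) and 4.38 for TPSAB1 (5.81).

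The number of genes at 1 TPM or more was lowest at 10894 in 1 concave library (group median 12794) and at 10624 in 1 convex library (12961), and the 10 highest genes took 32.4% of TPM in the same concave library (24.6%). Control replicates 2 and 3 had higher shares (41.1% and 33.9%) in a group that spread more widely, and without control replicate 2 the genes past the threshold for AIS against control were 740 in place of 345. Outside the comparisons, the first value of the 8 convex columns was 8.67 ± 3.58 (SD, n = 8). It belongs to no named gene after the move by 1 line and lies outside the fixed sum of its column, so what it measures is unknown.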

How the results depend on the processing

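All tests in this part were planned before the data were examined, except the fits with the gene names as deposited and without the 3 libraries with the fewest genes, which were chosen after seeing the data. List tests of each side against control were also not among the tests fixed beforehand. Over the alternatives run gene by gene and list by list, with the patients left out in turn counted once by the fit with the highest adjusted p, the named genes kept direction and side of the threshold in 991 comparisons, passed newly in 59, lost the call in 96 and reversed in 3, and the described lists did so in 211, 1, 1 and 11. Of the 991 and the 59, 51 and 14 came from the exact permutation of patients, adjusted over the 65 named genes only. These genes were picked from the same data, so the 14 are not passes at the threshold over all genes. The estimated correlation is not in this tally: with it every described list that had passed lost its call, except the immediate early list for convex against control. TPM keeps no depth, so no value could be tied to reads. Where no reason is given, the cause was not tested. The rescaling without mitochondrially encoded genes and their share per library could not be run, because the table holds none.

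Genes past the threshold moved by more than 1.5 times in these fits. AIS against control (345) gave 731 with median-of-ratios and 957 with quantile scaling, 1156 with the adipocyte and 29 with the immediate early mean as a covariate, and 1012 without the 3 libraries. The immediate early mean separates AIS from control, so this covariate takes up part of the difference itself and widens the errors: 46 of the 50 named genes called for AIS against control lost the call, with MYH1 at 4.19 ± 1.06 in place of 4.68 ± 0.61 (SE) and FOS at 2.47 ± 0.66 in place of 5.73 ± 0.64, while ACTC1, at −4.89 ± 0.82, passed (adjusted p = 0.0265). Concave against control (368) gave 205 without a filter, 755, 899, 2381, 116 and 567 in the same order. Convex against control (111) gave 31 without a filter, 184, 211, 0 with the immediate early covariate (limma; 2234 unadjusted) and 331 without the 3 libraries. Concave against convex (1) gave 3 without a filter, 7 with a minimum of 5 TPM, 3 with quantile scaling, 16 with array weights, 9 with the immediate early covariate, 46 with the patient as a random effect and 2 without the 3 libraries; its lists (18) fell to 9 with array weights. With an estimated correlation the lists were 0 in both comparisons (camera; 5 and 4 unadjusted). With the gene names as deposited the counts were 10097 for AIS against control, 15144 for concave against convex and 14587 for convex against control, as names and values of the convex columns then differ by 1 line. With separate controls, and so fewer for each side, the correlation of the sides' fold changes was 0.426.

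Leaving out 1 patient gave 246 to 740 genes for AIS against control (lowest without control replicate 5, highest without control replicate 2), 18 to 24 lists, 0 to 10 genes and 14 to 22 lists for concave against convex, 278 to 471 genes for concave against control and 76 to 186 for convex against control. 37 of 50 named genes called for AIS against control passed in every such fit. CLCN1 was lost without AIS replicate 2, 4, 6, 7, 8 or 9 or control 1, 2 or 5 (adjusted p up to 0.124), COX6A2 without AIS 2, 5, 6, 7, 8 or 10 or control 4 or 5 (0.0994), and MYH8 without AIS 4, 6, 7, 8 or 10 or control 1, 4 or 5 (0.120). DOK7 was lost without any of AIS 2 and 4 to 10 or control 1, 4 or 5 (0.129), MUSTN1 without AIS 2, 4, 6, 8 or 9 or control 2, 4 or 5 (0.126), and FNDC5 without AIS 2, 5, 6, 7, 8 or 10 or control 1, 3 or 4 (0.116).

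Directions turned as follows. The median of the oxidative phosphorylation list was −0.005 with array weights, −0.022 without the 3 libraries, −0.146 with the immediate early covariate and −0.023 without control replicate 3, where its call was lost (adjusted p = 0.347), as it was without AIS replicate 1 (0.0544) or control replicate 4 (0.0616). With the adipocyte covariate the adipocyte list was at −0.120, by construction, and the neutrophil and mast cell list at −0.384. With the immediate early covariate SOCS3 was at −0.768, ZFP36 at −0.067 and SELE at −0.355, and the list medians were −0.067 for immediate early, by construction, −0.979 for NF-kappaB, −0.679 for heat shock, −0.031 for excitation-contraction coupling and −0.337 for neutrophil and mast cell.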

Other observations

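The tests reported in this part on pairs of sides were chosen only after the result was seen. Gene lists beyond those described in the comparisons also differed between AIS patients and controls, at the preset correlation of camera and in none with an estimated correlation. The glucocorticoid response list had a median log2 fold change of 0.56 (4 of 16 members rose, over all genes and adjusted over the list alone; camera adjusted p = 4.44e-05, adjusted p = 0.490 with an estimated correlation), and it shares DUSP1 with the immediate early list. The circadian clock list had a median of 0.34 (0 of 17 passed, 1 adjusted over the list alone; 0.0010, adjusted p = 0.638 with an estimated correlation). The Schwann cell and nerve list had a median of 0.34 (1 of 12 rose, EGR2, which the immediate early list also holds; 1.44e-04, adjusted p = 0.606 with an estimated correlation). The cervical and anterior thoracic HOX list had a median of 0.25 (0 of 12 passed, also adjusted over the list alone; 0.0075, adjusted p = 0.638 with an estimated correlation) and the mid thoracic HOX list 0.48 (0 of 8 passed, 1 adjusted over the list alone; 0.0076, adjusted p = 0.388 with an estimated correlation). Sarcomere and Z-disc genes had a median of 0.28 (1 of 24 rose, 5 rose and 2 fell adjusted over the list alone; 5.09e-06, adjusted p = 0.606 with an estimated correlation).

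Markers of fibro-adipogenic progenitors were lower in AIS (median −0.62, 1 of 16 fell, 4 adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.768 with an estimated correlation). Macrophage and monocyte markers had a median of −0.58 (0 of 20 passed, also adjusted over the list alone; 0.0031, adjusted p = 0.797 with an estimated correlation), and lymphocyte markers −0.36 (1 of 12 fell, 2 adjusted over the list alone; 0.0293, adjusted p = 0.797 with an estimated correlation). Complement genes had a median of −0.50 (0 of 15 passed, 1 adjusted over the list alone; 0.0369, adjusted p = 0.805 with an estimated correlation). Genes near loci associated with scoliosis did not pass as a list (median 0.09, 0 of 25 members passed, camera adjusted p = 0.176), nor did satellite cell genes (median −0.05, 0 of 9, 0.682).

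In the 6 patients with both sides, the fast fibre mean was higher on the concave side in 6 of 6 (1.00 ± 0.65 on the log2 scale, SD) and the slow fibre mean was higher on the concave side in 1 of 6 (−0.42 ± 0.38, exact sign-flip p = 0.0625). MYH2, the myosin heavy chain of fast 2A fibres, was at 1734 ± 523 TPM on the concave and 1431 ± 699 TPM on the convex side (SD, n = 8 each). An exact permutation of the libraries without the pairs gave p = 0.243. In controls MYH2 was at 415 ± 531 TPM (n = 5).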
